A study of Caenorhabditis elegans with 6 samples.

How the data were processed

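Ribosome profiling sequences the stretches of mRNA that ribosomes protect, so that the reads over a coding sequence report how many ribosomes sit on it. Per the labels' protocols, synchronized eggs were placed on plates with or without CHX, ribosomes were pelleted from worm lysate through 34% sucrose, RNA fragments of 26 to 34 nucleotides were taken from a gel, and libraries were made with the D-Plex Small RNA-seq kit. The deposited table holds raw counts of footprint reads per gene, 1 line for each of 20189 protein-coding genes, with every line marked as coding sequence per the file headers. The submitters' processing notes name DESeq2 and the genome build WBcel235. The aligner, the removal of rRNA reads, the treatment of molecular identifiers, strand and reads with several matches are not given in the sources used here. Genes with near-identical copies (major sperm proteins, histones, actins, some collagens and P-glycoproteins) and overlapping or antisense genes are therefore uncertain. The table's length column equals end minus start on the genome and so contains introns, and it was used only as a genomic span. Positions of the 10 mitochondrial-DNA genes were taken from the transcript headers. Gene symbols are those of the table.

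The 6 libraries fall into 2 groups by the treatment in the labels, no CHX and CHX, with 3 replicates each. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be partly technical. No libraries were near-duplicates: the chi-square statistic per degree of freedom over genes was 2.00 to 3.69 between libraries of a group and 15.6 to 19.5 between groups. Totals ran from 1601009 to 1901815 reads, and 3208 genes had no read in any library. Such depth limits what can be seen for weakly translated genes, and counting intervals and floors cover counting error only.

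Genes were kept with edgeR's filterByExpr (minimum count 10), which left 10632. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3 on the 6 libraries with group as the only term. Benjamini-Hochberg adjusted p-values under 0.05 were called. The biological coefficient of variation was 11.1%. CPM values are TMM-normalised, and error is the SD over 3 libraries. Fold changes are given as log2 of CHX over no CHX. A group without reads was set to a floor of 3 reads over the group, and ratios of genes with 1 to 3 reads in a group have an exact (Clopper-Pearson) 95% counting interval. In counts simulated from these libraries for this comparison, with 10360 genes in the step and 200 of them changed, edgeR recovered 17.9% of 1.5-fold, 71.6% of 2-fold and 92.4% of 4-fold changes, and called 0.0767% of unchanged genes.

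The 30 gene lists were fixed before the data were examined, as patterns on gene symbols, and none came from these samples. They hold 1420 tested genes, 10 of which stand on more than 1 list. Each list was tested with camera in limma 3.58.1 with the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation and with fry. Members were counted as risen or fallen at an adjusted p under 0.05 over all genes and, again, adjusted over the list alone. Camera asks whether a list moved relative to other genes.

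The named genes were also chosen by a rule set before the data were examined. It took rpl-36.A, the 12 largest rises and 12 largest falls among called genes with mean CPM of at least 10, full separation of the groups and a symbol of letters and a number, up to 2 risers and 2 fallers per list (or the member with the smallest p), and the 5 genes with the most reads. Genes with only a sequence name ranked above the last of these 12 in 10 cases for rises and 5 for falls. The genes mbk-2, pqn-53, hsp-4, hsp-70 and hsp-16.2, and the members of the symbol families given among the other observations, were chosen after their values were seen.

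Alternatives were the median-of-ratios size factors, upper-quartile factors, no filter on low counts, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out the 100 most abundant genes, a test against a 1.5-fold change, summing near-identical families, and leaving out each library in turn. Random lists matched on mean CPM and genomic span were drawn 10000 times from the 40 nearest genes of each member. GC content and coding length were not analysed here, as no genome sequence was used.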

Results

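Ribosome footprints were counted over the coding sequence of 20189 protein-coding genes in 6 libraries from whole Caenorhabditis elegans at the L4 larval stage. Every library came from hermaphrodites that carried 1 copy of rpl-36A with the P55Q change over the mIn1 balancer, a rearranged chromosome II that keeps the mutation heterozygous. The gene encodes the ribosomal protein eL42 of the large subunit, and changes of this conserved proline are known to make ribosomes resistant to cycloheximide (CHX), a drug that blocks translation elongation. In the first group, 3 libraries came from animals grown without the drug for 2 days (no CHX). In the second, 3 came from animals grown from eggs on plates with 500 µg/ml of CHX for 3 days (CHX), so that both groups were collected at L4. All were kept at 23 °C. Because culture time went with treatment, every difference given here is between animals that differed in both.

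The libraries held 1639682, 1786600 and 1842865 reads in no CHX replicates 1 to 3, and 1740161, 1601009 and 1901815 in CHX replicates 1 to 3. Spearman correlations of gene levels ran from 0.969 to 0.974 between libraries of a group and from 0.944 to 0.951 between groups. The first principal component held 73.7% of the variance and separated the groups. The second held 8.57% and set no CHX replicate 3 (score -25.75) apart from no CHX replicate 1 (score 19.35).

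The comparison asked how footprints differ between larvae that reached L4 with CHX and those that did so without it. Most genes of the oocyte and eggshell rose, among them the eggshell genes cpg-1 and cpg-2, and so did many antimicrobial genes such as dod-24 and lys-7. Most genes of sperm, of ribosome biogenesis and of mitochondrial respiration fell, as did the fat metabolism genes acdh-2 and fat-7. Of 10632 genes tested, 2364 rose and 2123 fell with CHX, which together are 42.2% (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 1014 risers and 508 fallers, and at least 4-fold changes for 356 and 59. The median change of a called gene was 1.72-fold, and in 52.5% of all tested genes all 3 libraries of one group lay above all 3 of the other, against 10% expected by chance. Without matched mRNA libraries, which were not used here, a footprint change cannot be divided into mRNA level and translation. Counts per gene also do not tell elongating ribosomes from ribosomes held in place by CHX.

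The mutated gene itself, rpl-36.A (WBGene00004454, WBcel235 chromosome II, 11096542 to 11097204, minus strand), had 911, 879 and 1006 CPM (counts scaled to the library total with TMM) in no CHX replicates 1 to 3. It had 586, 719 and 668 CPM in CHX replicates 1 to 3. The mean fell from 932 ± 66.4 CPM to 658 ± 67.4 CPM (SD, n = 3 each), a log2 fold change of -0.50 (SE 0.098, edgeR adjusted p = 5.0e-04). The counts do not tell the mutant from the balancer copy. The drop was tested against no change, and it did not pass a test against 1.5-fold.

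Genes of the oocyte and eggshell showed the largest shift of the 30 gene lists. Of 31 members tested, 29 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 2.80 (camera adjusted p = 9.0e-50, or adjusted p = 0.199 with an estimated correlation). The chondroitin proteoglycans of the eggshell, cpg-1 and cpg-2, rose from 67.3 ± 23.9 to 1177 ± 122.6 CPM and from 59.0 ± 17.5 to 1031 ± 56.7 CPM (SD, n = 3 each; log2 fold changes 4.12 and 4.13). The zinc finger gene oma-2, needed for oocyte maturation, rose from 4.70 ± 1.69 to 81.8 ± 4.56 CPM (4.10), and the caveolin gene cav-1 rose by 4.29 on the log2 scale. The list took 0.271%, 0.228% and 0.277% of reads in the no CHX libraries and 0.897%, 0.993% and 0.977% in the CHX libraries. The members mbk-2 (-0.11) and pqn-53 (-0.01) did not pass.

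Sperm genes moved the other way. Of 66 members tested, 48 fell and 2 rose (51 and 2 when adjusted over the list alone), with a median of -0.81 (camera adjusted p = 4.8e-11, or adjusted p = 0.378 with an estimated correlation). The gene of the spermatogenesis transcription factor SPE-44 fell by 2.90 on the log2 scale, from 13.2 ± 2.99 to 1.77 ± 1.30 CPM (SD, n = 3 each). The risers were sss-1 (1.895) and spe-39 (0.88), the latter a gene of lysosome-related vesicle traffic that acts in many tissues. The major sperm protein gene msp-152 had a log2 fold change of -2.09, but its copies are near-identical and can share reads. Summed as 1 feature, msp genes fell from 1054 ± 125 to 589 ± 86.2 CPM (-0.84, edgeR adjusted p = 2.7e-05). Among 20 sperm genes outside such families, 12 fell and 1 rose, with a median of -0.88. The call of spe-39 ended without no CHX replicate 1 (0.71, edgeR adjusted p = 0.0719) or CHX replicate 1 (0.72, edgeR adjusted p = 0.0652).

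The list of germline mitosis, meiosis and P granule genes went both ways. Of 53 members, 17 rose and 9 fell, with a median of 0.09 that did not pass (camera adjusted p = 0.415), and 11 rose without CHX replicate 2 and 11 with DESeq2. The replicative helicase genes mcm-3 and mcm-6 rose by 1.73 and 1.59 on the log2 scale, and the Piwi gene prg-1 and the meiotic chromosome axis gene him-3 fell (-0.90 and -0.82). Of 23 histone genes, 4 rose and 4 fell (median 0.08, camera direction lower, adjusted p = 0.650), among them the linker histones hil-1 (1.88), hil-3 (1.04) and hil-5 (-1.35) and the histone H3 gene his-70 (-2.64), whose family can share reads. Without the filter on low counts, 7 of 40 histone genes rose. No yolk protein gene of the 6 vitellogenins passed with edgeR, 1 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 0 with limma-voom. The most abundant, vit-6, had 4709 ± 687 and 5815 ± 2683 CPM without and with CHX (log2 fold change 0.30, edgeR adjusted p = 0.565), and vit-2 had a log2 fold change of 0.72 (edgeR adjusted p = 0.0725). CHX replicate 2 stood apart for both, with 8910 CPM of vit-6 against 4139 and 4396 in the other CHX libraries. Without it 1 vitellogenin rose and 4 fell, the list passed and its median moved from -0.60 to -1.37. Without CHX replicate 1, 1 rose, and the median was -0.31 without CHX replicate 1 and -0.33 without CHX replicate 3.

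**Figure D1:**
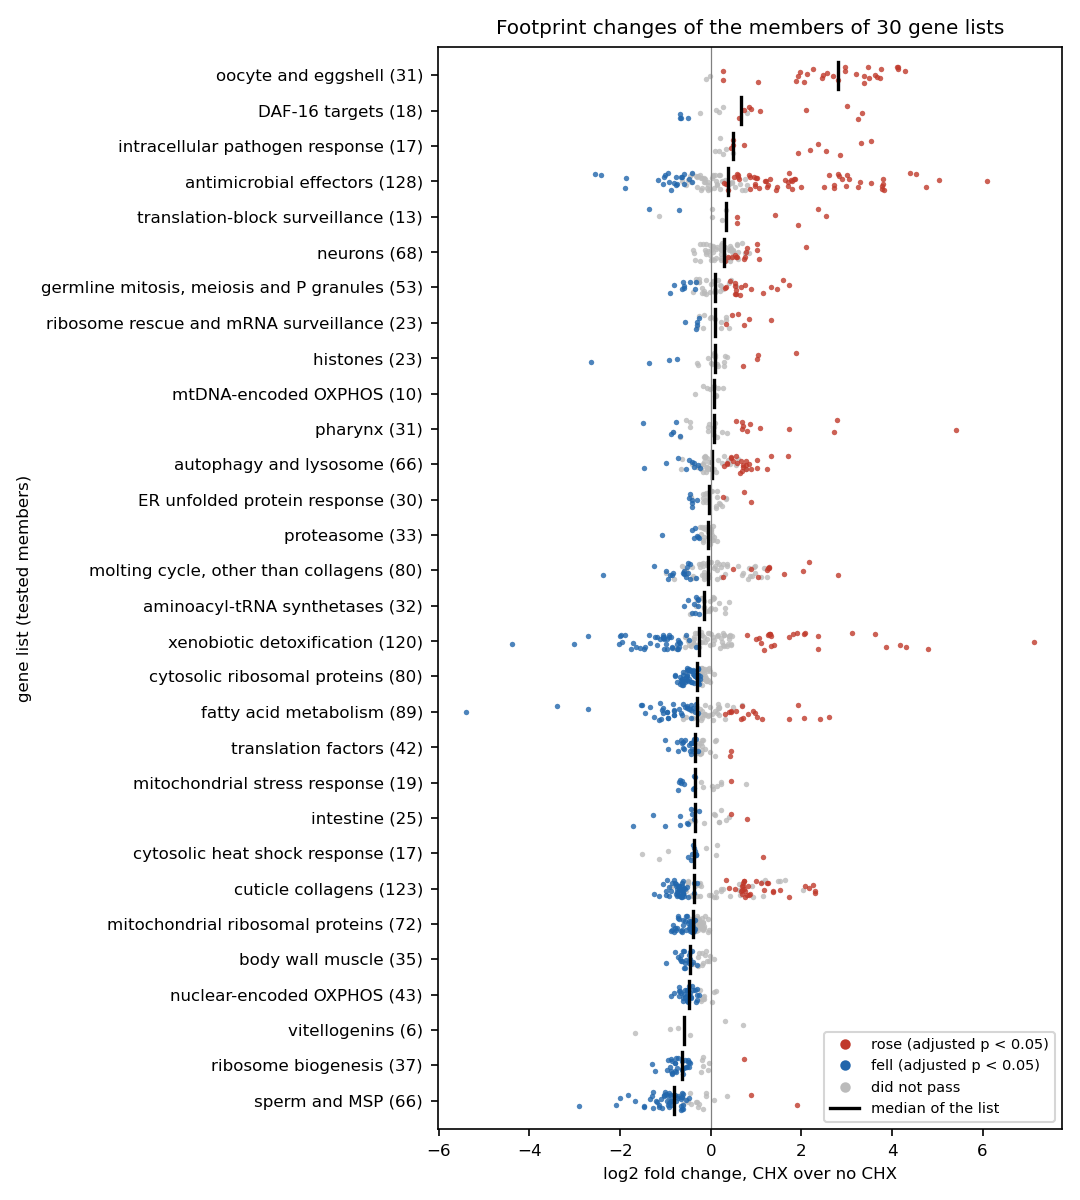
Each point is 1 tested gene, placed by its log2 fold change of CHX over no CHX (horizontal axis) within its gene list (vertical axis, number of tested members in brackets); red and blue points rose or fell at an adjusted p under 0.05 over all genes, and black bars are list medians. The oocyte and eggshell list has the highest median, 2.80, and the sperm list the lowest, -0.81.

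Antimicrobial effector genes rose as a group. Of 128 tested, 57 rose and 22 fell (60 and 24 when adjusted over the list alone), with a median of 0.38 (camera adjusted p = 8.6e-07, or adjusted p = 0.199 with an estimated correlation). The innate immune effector dod-24 rose from 20.6 ± 4.82 to 555 ± 20.1 CPM (SD, n = 3 each; log2 fold change 4.76, edgeR adjusted p = 1.6e-13). The lysozyme gene lys-7 rose from 132 ± 25.4 to 1252 ± 125 CPM (3.24). Genes with C-type lectin domains were among the largest rises, with log2 fold changes of 4.401 for clec-190 and 3.81 for clec-91. For clec-42 there were 238 reads in the CHX libraries and 3 in the no CHX libraries, a ratio of 76.4 (95% counting interval 25.8 to 373), and for clec-60 there were 46 and 1 (ratio 44.3, interval 7.56 to 1790). Without the filter on low counts the median of the list was 0.19 over 275 genes. The saposin-like genes spp-4 and spp-17 fell (log2 fold changes -2.55 and -2.43). The list took 1.32%, 1.34% and 1.18% of reads in the no CHX libraries and 2.13%, 2.02% and 2.19% in the CHX libraries.

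The intracellular pathogen response, a transcriptional program set off by microsporidia and virus, was higher with CHX. Of 17 members 11 rose and none fell, also when adjusted over the list alone (median 0.49, camera adjusted p = 8.5e-06, or adjusted p = 0.199 with an estimated correlation). The genes pals-32 and pals-14 rose by 3.54 and 3.32 on the log2 scale, pals-32 from 3.17 ± 1.37 to 37.2 ± 2.71 CPM (SD, n = 3 each). The median was 0.77 without no CHX replicate 1 and 0.87 without no CHX replicate 2, and without the filter on low counts it was 1.24 over 43 genes.

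Genes known to respond to blocked translation moved unevenly. Of 13 such surveillance genes, 6 rose and 2 fell, with a median of 0.33 that did not pass (camera adjusted p = 0.0737). The infection response gene irg-2 and the transporter gene pgp-5 rose by 2.54 and 2.37 on the log2 scale, while the glutathione S-transferase gene gst-4 (-1.36) and the bZIP transcription factor gene zip-3 (-0.70) fell. The list passed without the filter on low counts (adjusted p = 0.031), with fry (adjusted p = 0.0238) and without no CHX replicate 2 (median 0.45), no CHX replicate 3 (0.57) or CHX replicate 3 (0.47), and its median was 0.04 without no CHX replicate 1 and 0.12 without CHX replicate 1. The zip-3 call ended without no CHX replicate 2 (-0.53), CHX replicate 1 (-0.65) or CHX replicate 3 (-0.66).

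Of 18 targets of DAF-16, the FOXO factor of insulin signalling, 9 rose and 4 fell (median 0.67, camera adjusted p = 0.0026, or adjusted p = 0.202 with an estimated correlation). The median was 0.38 without CHX replicate 1, and the fallers numbered 2 without no CHX replicate 2, 1 without CHX replicate 2 and 1 without CHX replicate 3. The risers included dod-3 (3.33) and lys-7 (3.24), which is also on the antimicrobial list. The list was not split by whether DAF-16 raises or lowers a gene, so its median does not report DAF-16 activity. The fallers included the mitochondrial transhydrogenase gene nnt-1 (-0.69) and the metallothionein gene mtl-2 (-0.68). The nnt-1 call ended without no CHX replicate 2 (-0.66), CHX replicate 2 (-0.53) or CHX replicate 3 (-0.60). The mtl-2 call ended without any library but no CHX replicate 1, with values from -0.76 without no CHX replicate 2 to -0.57 without no CHX replicate 3.

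Genes that build ribosomes fell. Of 37 ribosome biogenesis genes tested, 30 fell and 1 rose, also when adjusted over the list alone, with a median of -0.64 (camera adjusted p = 1.4e-10, or adjusted p = 0.199 with an estimated correlation). The rRNA methyltransferase gene fib-1 (fibrillarin) fell from 950 ± 76.3 to 383.6 ± 30.04 CPM (SD, n = 3 each; log2 fold change -1.31, edgeR adjusted p = 1.5e-08). The snoRNP gene nol-56 fell from 708 ± 21.2 to 302 ± 12.6 CPM (-1.23). The riser was nop-1 (0.74), which in worms acts in the cell cortex of embryos and not in the nucleolus. The list took 0.714%, 0.657% and 0.682% of reads without CHX and 0.415%, 0.411% and 0.432% with it.

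Cytosolic ribosomal protein genes also fell. Of 80 tested, 50 fell and none rose (53 fell when adjusted over the list alone), with a median of -0.30 (camera adjusted p = 5.6e-09, or adjusted p = 0.588 with an estimated correlation). Against a 1.5-fold change, 2 of the 80 still fell. The largest falls were rpl-34 (-0.80) and rpl-25.2 (-0.79), and the mutated rpl-36.A at -0.50 lay within the range of the list. The list took 8.24%, 7.62% and 8.28% of reads without CHX and 6.43%, 6.79% and 6.97% with it. Random lists of genes matched on mean CPM and genomic span had a median change of -0.30 as well. Without the 100 most abundant genes, 42 of the 54 members left fell, with a median of -0.42. Abundant genes fell more often than weak ones. Among the 1064 genes with the highest CPM, 44.9% fell and 16.4% rose, with a median of -0.23. Among the 1064 with the lowest CPM, 11.3% fell and 20.1% rose, with a median of 0.17.

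**Figure D2:**
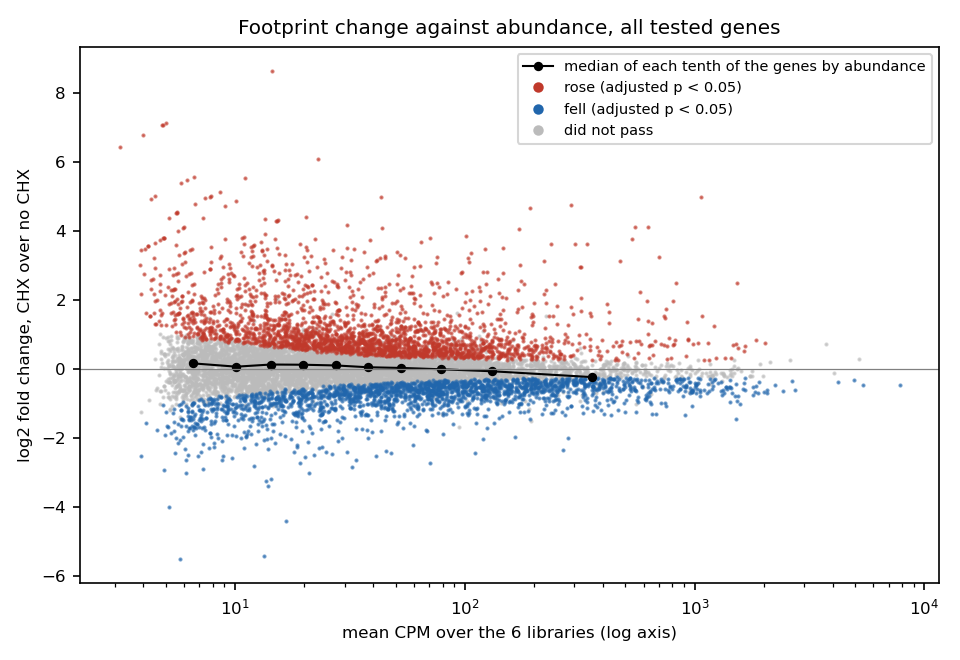
Each point is 1 of the 10632 tested genes, placed by its mean CPM over the 6 libraries (horizontal log axis) and its log2 fold change of CHX over no CHX (vertical axis), coloured by whether it rose or fell at an adjusted p under 0.05; black dots are medians of 10 equal parts of the genes by CPM. The medians run from 0.17 at the lowest CPM to -0.23 at the highest, and the fitted values of 6 genes without a read in the no CHX libraries depend on the prior count.

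Of 42 translation factor genes, 23 fell and 2 rose (26 and 2 when adjusted over the list alone; median -0.34, camera adjusted p = 1.9e-05, or adjusted p = 0.378 with an estimated correlation). Of random lists matched on mean CPM and genomic span, 96.4% had a higher median, which put the list within their central 95%. The eIF5A genes iff-1 and iff-2 fell (-1.02 and -0.95). The elongation factor gene eef-1A.1, which had the most reads of all genes, fell from 9135 ± 482 to 6709 ± 301 CPM (SD, n = 3 each; -0.45). The risers were the cap-binding gene ife-3 (0.44) and eif-2D (0.43), and the call of eif-2D ended without any 1 of no CHX replicates 1 to 3 (0.38, 0.43 and 0.36) or without CHX replicate 2 (0.35). Of 32 aminoacyl-tRNA synthetase genes, 10 fell and none rose (median -0.15, camera adjusted p = 0.0877), with kars-1 at -0.50 and wars-1 at -0.58; 6 fell without CHX replicate 1, 6 without CHX replicate 2 and 6 with the replicate block. That list passed without no CHX replicate 2 (median -0.22), without the filter on low counts (adjusted p = 0.031), with limma-voom (adjusted p = 0.0227) and with fry (adjusted p = 0.0168). Of 23 genes of ribosome rescue and mRNA surveillance, 6 rose and 5 fell (6 and 6 when adjusted over the list alone; median 0.09, camera adjusted p = 0.870). The nonsense-mediated decay genes smg-7 (1.33) and smg-8 (0.85) rose, and the genes rack-1 (-0.33), for a protein of the small ribosomal subunit, and abcf-2 (-0.58) fell. Without no CHX replicate 1, 3 rose and 3 fell, without no CHX replicate 2, 3 rose, and 2 fell without CHX replicate 1 and 3 without CHX replicate 3. With DESeq2, 3 rose and 3 fell, and with the replicate block 2 fell.

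Many nuclear genes of mitochondrial respiration and of the mitochondrial ribosome fell. Of 43 nuclear-encoded genes of oxidative phosphorylation, 33 fell and none rose (36 fell when adjusted over the list alone; median -0.47, camera adjusted p = 5.6e-08, or adjusted p = 0.378 with an estimated correlation), led by the complex III gene ucr-2.2 (-0.88) and the ATP synthase gene asb-2 (-0.82). Of 72 mitochondrial ribosomal protein genes, 36 fell and none rose (41 fell when adjusted over the list alone; median -0.39, camera adjusted p = 7.9e-07, or adjusted p = 0.378 with an estimated correlation), with mrps-14 at -0.89 and mrpl-17 at -0.87; 22 fell without CHX replicate 1 and 22 with DESeq2. None of 10 mitochondrial-DNA genes passed with edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 with edgeR. The one with the smallest p was nduo-3 (-0.34, edgeR adjusted p = 0.319). Their median was 0.08 and their mean 0.02, although camera placed the list below other genes (adjusted p = 0.831). Footprints of mitochondrial ribosomes are few in these libraries, at 0.0215% to 0.0428% of reads.

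Of 19 genes of the mitochondrial stress response, 10 fell and 1 rose (11 and 1 when adjusted over the list alone; median -0.35, camera adjusted p = 0.0471, or adjusted p = 0.378 with an estimated correlation). The fallers timm-17B.1 (-0.73) and tomm-22 (-0.70) encode parts of the protein import machinery, and the riser met-2 (0.44) encodes a histone methyltransferase. The call ended without CHX replicate 1 (median -0.30, camera adjusted p = 0.0957), with the replicate number as a block (adjusted p = 0.0587) and without the 100 most abundant genes (adjusted p = 0.0817).

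Of 17 cytosolic heat shock response genes, 9 fell and 1 rose (10 and 1 when adjusted over the list alone), with a median of -0.37 that did not pass (camera adjusted p = 0.111) but did without no CHX replicate 1 (-0.45) or 2 (-0.49). It also passed without the filter on low counts (adjusted p = 0.0374), with DESeq2 (adjusted p = 0.0498) and with limma-voom (adjusted p = 0.0195). No CHX replicate 3 stood apart for chaperones. It had 6794 CPM of hsp-1 against 5153 and 4790 in the other no CHX libraries, and 5822 CPM of hsp-90 against 4504 and 4009. With it, hsp-1 and hsp-90 had log2 fold changes of -0.33 and -0.37 (edgeR adjusted p = 0.0289 and 0.0188), and without it -0.21 and -0.25 (edgeR adjusted p = 0.0951 and 0.0506). The co-chaperone gene ahsa-1 moved from -0.43 to -0.26 without it, and 5 of the 17 then fell; its call also ended without CHX replicate 1 (-0.41) or 3 (-0.36). Both hsp-1 and hsp-90 also missed the threshold without CHX replicate 1 or 3, and hsp-1 without CHX replicate 2, with values from -0.34 to -0.31 for hsp-1 and -0.36 for hsp-90. The fallers numbered 4 without CHX replicate 1 and 4 without CHX replicate 3. The Hsp70-family gene hsp-110 fell by 0.51 on the log2 scale, and the small heat shock protein gene hsp-43 rose by 1.16.

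Of 30 genes of the endoplasmic reticulum unfolded protein response, 3 rose and 6 fell (median -0.05, camera adjusted p = 0.561). The sensor genes pek-1 (0.89) and atf-6 (0.73) rose, and manf-1 (-0.45) and the translocon-associated gene trap-2 (-0.49) fell. The BiP gene hsp-4 had 3247 CPM in no CHX replicate 3 and 1049 and 1192 in the other no CHX libraries, against 2201, 1526 and 1570 with CHX, and it did not pass (edgeR adjusted p = 0.953). Without no CHX replicate 3, 7 members rose. Of 33 proteasome genes, 7 fell and none rose (5 fell when adjusted over the list alone; median -0.06, camera adjusted p = 0.112), with the paralog rpn-6.2 at -1.07 and the base ATPase rpt-6 at -0.42, and 4 fell without CHX replicate 1. The proteasome list passed without no CHX replicate 1 (median -0.18), without the filter on low counts (adjusted p = 0.0386) and with limma-voom (adjusted p = 0.0346).

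Genes of fat metabolism changed in both directions. Of 89 tested, 38 fell and 18 rose (40 and 18 when adjusted over the list alone; median -0.31, camera adjusted p = 0.016, or adjusted p = 0.437 with an estimated correlation). Tested against a 1.5-fold change, 9 rose and 9 fell. The acyl-CoA dehydrogenase gene acdh-2 had 137 reads in the no CHX libraries and 3 in the CHX libraries, a ratio of no CHX over CHX of 47.4 (95% counting interval 15.9 to 233). The stearoyl-CoA desaturase gene fat-7 fell from 26.2 ± 3.59 to 2.46 ± 0.351 CPM (SD, n = 3 each; log2 fold change -3.38). The acyl-CoA oxidase gene acox-1.2 had a log2 fold change of -2.71 (edgeR adjusted p = 0.0485). Its call ended without no CHX replicate 2 or any CHX library, with values from -2.77 without CHX replicate 2 to -2.62 without CHX replicate 1. The lysosomal lipase gene lipl-1 and the acyl-CoA synthetase gene acs-3 rose by 2.61 and 2.42 on the log2 scale. Outside the lists, large falls were found for the adenine nucleotide translocator genes ant-1.4 (-2.84) and ant-1.3 (-2.42), the glycerol synthesis gene gpdh-1 (-2.52) and uggt-2 (-2.50), for a glucosyltransferase of glycoprotein folding. The secreted SCP-domain gene scl-2 rose from 19.4 ± 8.55 to 323 ± 31.7 CPM (SD, n = 3 each; 4.06).

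Detoxification genes changed in both directions. Of 120 genes for cytochrome P450s, glucuronosyltransferases, glutathione S-transferases and P-glycoproteins, 26 rose and 44 fell (29 and 47 when adjusted over the list alone; median -0.25, mean 0.00, camera adjusted p = 0.112), and the list passed without no CHX replicate 1 (-0.24). Without the filter on low counts the median turned to 0.03 over 192 genes. The cytochrome P450 gene cyp-33B1 rose by 4.17 on the log2 scale, whereas cyp-35A3, cyp-35A5 and cyp-35C1 fell (-4.397, -3.02 and -2.72). The glucuronosyltransferase genes ugt-24 and ugt-31 rose by 4.31 and 3.87, and ugt-18 had 68 reads with CHX and 2 without (ratio 32.7, 95% counting interval 8.72 to 276). The P-glycoprotein gene pgp-7 had 53 reads with CHX and 0 without, at least 17.8-fold higher against a floor of 3 reads over the group. Its neighbours in the family are similar in sequence and can share reads. The median of the list stayed at -0.25 with pgp-7 set to that bound.

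**Figure D3:**
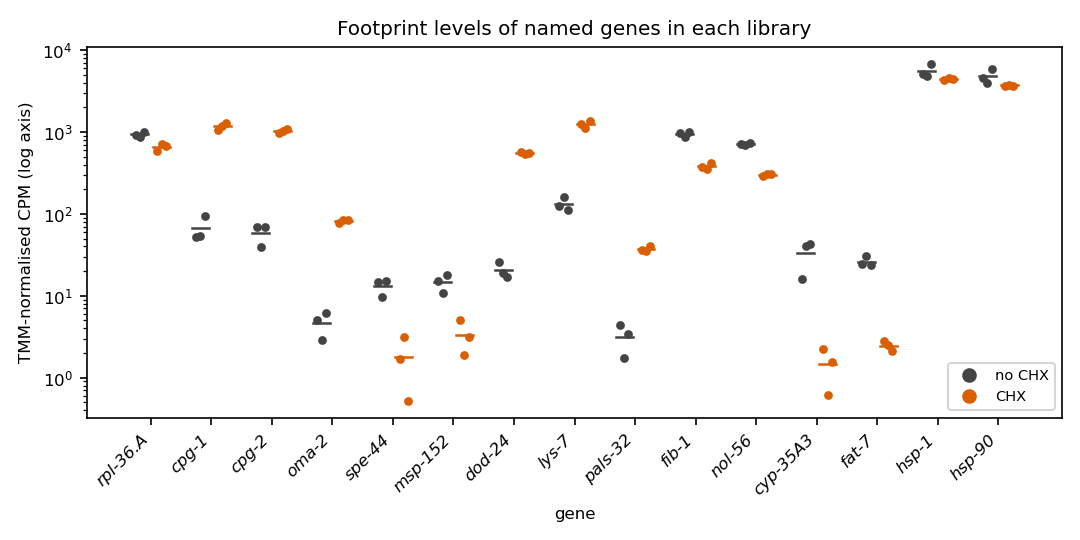
Points are the TMM-normalised CPM (vertical log axis) of 15 named genes (horizontal axis) in the 3 no CHX libraries (grey) and the 3 CHX libraries (orange), and short lines are group means. For rpl-36.A the means are 932 and 658 CPM, and for cpg-1 they are 67.3 and 1177 CPM.

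Somatic tissues were followed through marker genes. Of 35 body wall muscle genes, 22 fell and none rose (24 fell when adjusted over the list alone; median -0.45, camera adjusted p = 7.8e-07, or adjusted p = 0.199 with an estimated correlation), with troponin I tni-1 at -0.995, the calponin-like clik-1 at -0.79 and the myosin heavy chain unc-54 at -0.46. The actin genes on this list are near-identical, and summed as 1 feature they fell by 0.59 on the log2 scale. Muscle genes were not compared with lists matched on mean CPM, and abundant genes as a whole fell more often. Of 68 neuronal genes, 14 rose and none fell (9 rose when adjusted over the list alone; median 0.29, camera adjusted p = 0.117), led by the insulin-like gene ins-7 (2.09), which is also on the list of DAF-16 targets. The neuropeptide gene flp-5 (1.07) lost its call without any library but no CHX replicate 2, with values from 0.76 to 1.16. Between 8 and 9 neuronal genes rose without any 1 of the no CHX libraries or without CHX replicate 1, and 3 rose with DESeq2. The neuronal list passed with limma-voom (adjusted p = 0.0227) and fry (adjusted p = 0.016). Of 25 intestinal genes, 11 fell and 2 rose (12 and 2 when adjusted over the list alone; median -0.35, camera adjusted p = 0.0529). The list passed without no CHX replicate 3 (median -0.54) or CHX replicate 3 (-0.46), and 7 fell without CHX replicate 2. It also passed with median-of-ratios (adjusted p = 0.0481) or upper-quartile factors (0.0474), without the filter on low counts (0.0146), with DESeq2 (0.0168) or limma-voom (0.0334), and with near-identical families summed (0.045). The acid phosphatase gene pho-1 fell by 1.27 on the log2 scale, and the acid ceramidase gene asah-1 rose by 0.80. The transporter gene pgp-1 had -1.73, and its call ended without CHX replicate 1 (-1.69), 2 (-1.89) or 3 (-1.60), as did that of ifo-1 (0.44) without no CHX replicate 2 (0.40) or CHX replicate 1 (0.34). Of 31 pharyngeal genes, 11 rose and 5 fell (median 0.07, camera adjusted p = 0.353), and 8 fell without CHX replicate 3. There, pqn-60 rose (2.79), pqn-74 fell (-0.87), pqn-2 fell from 10.8 ± 1.09 to 3.71 ± 1.33 CPM (SD, n = 3 each), and phat-5 had 60 reads with CHX and 1 without (ratio 57.8, 95% counting interval 9.98 to 2320).

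Cuticle collagen genes split. Of those tested, 32 rose, 48 fell and 43 did not pass (35 rose and 51 fell when adjusted over the list alone), and the median was -0.37 although the mean was 0.04 (camera adjusted p = 0.0432, or adjusted p = 0.378 with an estimated correlation). Tested against a 1.5-fold change, 8 rose and 9 fell. The fallers included col-154 (-1.26) and col-170 (-1.14), and the risers included col-98 (2.29) and col-103 (2.29), whose call ended without no CHX replicate 3 (2.32, edgeR adjusted p = 0.0559). The call of the list ended without no CHX replicate 1 (-0.31) or 2 (-0.36), CHX replicate 2 (-0.28) or CHX replicate 3 (-0.35). Of 80 other molting cycle genes, 12 rose and 17 fell (11 and 17 when adjusted over the list alone; median -0.07, mean 0.11, camera adjusted p = 0.353). The fibrillin-like fbn-1 (2.16) and mltn-1 (2.80) rose, the hedgehog-related grl-27 (-2.38) fell, and wrt-4 (-1.26) did so except without no CHX replicate 3 (-1.18, edgeR adjusted p = 0.0544). Of 66 genes of autophagy and the lysosome, 23 rose and 10 fell (median 0.04, camera adjusted p = 0.353), and 6 fell without CHX replicate 1. The cathepsin B-like protease genes cpr-1 (1.69) and cpr-4 (1.33) rose, cpr-8 fell by 0.99 on the log2 scale, and the aspartic protease gene asp-17 fell by 1.48.

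Across the 30 lists, 4 passed as higher and 10 as lower with the preset correlation, and none passed with correlations estimated from the 6 libraries, where 6 had an unadjusted p under 0.05. With fry, which tests each list by itself, 17 passed. Adjusted over the list alone, the counts of risers and fallers were the same as over all genes for the lists of germline genes, histones, translation-block surveillance, DAF-16 targets, aminoacyl-tRNA synthetases, endoplasmic reticulum stress, pharynx, autophagy, mitochondrial DNA and vitellogenins.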

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

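None of the called named genes and called lists changed direction under the alternatives run, whereas medians near 0 of lists that did not pass could change sign, as for mitochondrial-DNA genes (-0.10 without CHX replicate 1, 0.28 without CHX replicate 2) and detoxification genes (0.03 without the filter on low counts). No gene called in both the reported and an alternative analysis had opposite signs. Tested against a 1.5-fold change, 913 genes rose and 484 fell, fewer because the test asks for a larger change. There, 27 of 31 oocyte and eggshell genes rose, and 8 of 37 ribosome biogenesis genes fell. Only 2 of 80 cytosolic ribosomal protein, 1 of 72 mitochondrial ribosomal protein and 2 of 43 oxidative phosphorylation genes fell. Falls numbered 2 of 42 for translation factors, 2 of 35 for body wall muscle and 0 of 19 for mitochondrial stress. With correlations estimated from the 6 libraries, 0 of the 30 lists passed, where the estimated correlations, 0.0163 to 0.960, exceed the preset 0.01. In that test, a shift of -0.40 simulated in 1 list of 40 genes, among 99 unchanged lists, missed the threshold (camera adjusted p = 0.0784). The preset correlation (camera adjusted p = 1.5e-17) and fry (adjusted p = 0.0321) called that list. Genes were simulated independently of each other, so these calls do not show how either test behaves on lists of correlated genes. The simulated values were adjusted over more lists than the 30 here, so the miss does not show low power over the 30. The simulation thus does not decide why no list passed with estimated correlations. Medians are the same there: 2.80 for oocyte and eggshell, -0.81 for sperm, -0.64 for ribosome biogenesis, -0.30 for cytosolic ribosomal proteins, -0.47 for nuclear-encoded oxidative phosphorylation, -0.45 for body wall muscle, -0.39 for mitochondrial ribosomal proteins, 0.38 for antimicrobial effectors, 0.49 for the intracellular pathogen response, -0.34 for translation factors, 0.67 for DAF-16 targets, -0.31 for fatty acid metabolism, -0.37 for cuticle collagens and -0.35 for the mitochondrial stress response.

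The mitochondrial stress list missed the threshold with the replicate block (median -0.35) and without the 100 most abundant genes (-0.29), and its median ran from -0.39 to -0.30 when 1 library was left out. The cuticle collagen list did so with upper-quartile factors (-0.40) and without the 100 most abundant genes (-0.29), with medians from -0.42 to -0.28 when 1 library was left out. Lists that did not pass in the reported analysis did so without the filter on low counts (aminoacyl-tRNA synthetases, proteasome, heat shock, translation-block surveillance and intestine), with DESeq2 (heat shock and intestine), with limma-voom (aminoacyl-tRNA synthetases, proteasome, heat shock, neurons and intestine), with fry (aminoacyl-tRNA synthetases, translation-block surveillance and neurons), and, for the intestine, with other scaling or summed families. The cause was not tested.

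Of the other counts, risers ran from 1889 to 2193, fallers from 1810 to 2221, 2-fold changes from 1559 to 1725 and called lists from 13 to 16 when 1 library was left out. DESeq2 called 3343 genes, of which 3301 were among the 4487 reported. Scaling moved the median of all genes by at most 0.03 on the log2 scale and the share of risers among calls from 52.7% to 49.0%. The replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.22, -0.14 and -0.13 across genes. The replicate block, shown for completeness, called 3999 genes, 2124 higher and 1875 lower, with 1496 changed at least 2-fold and 13 lists. Since all genes in the table are protein-coding, the alternative with only such genes changes nothing and was not run. At this depth, 17.9% of simulated 1.5-fold changes were recovered when 200 of 10360 genes were changed, a share that does not carry over to data with 4487 calls, where the adjusted threshold is less strict.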

Other observations

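Several families defined by gene symbol, some with members on the lists, held more risers or fallers than tested genes as a whole, and the family tests, the germline share test and the matched-list tests for ribosome biogenesis, mitochondrial ribosomal proteins, oxidative phosphorylation and translation factors were chosen after the result was seen. Over all symbol families of at least 8 tested genes (252 one-sided Fisher's exact tests), 19 tests passed after Benjamini-Hochberg adjustment. These tests take the members of a family as independent, whereas no gene list passed once correlations were estimated. They also do not match abundance: 19.97% of all tested genes fell, but 44.9% of the 1064 most abundant did. The p-values below are therefore a ranking of families and not evidence that a family moved apart from its abundance or as a unit. All 8 cct genes, which encode the subunits of the chaperonin that folds actin and tubulin, fell (median log2 fold change -0.34, Fisher adjusted p = 7.9e-05), from -0.28 for cct-2 to -0.68 for cct-6. Of 47 transthyretin-like ttr genes, 26 rose and 6 fell (median 0.62, Fisher adjusted p = 3.1e-05), with ttr-23 at 3.01 and ttr-50 at 2.87. Acyl-CoA dehydrogenase genes (acdh) fell in 10 of 13 cases (median -0.81, Fisher adjusted p = 4.4e-04), and fatty acid elongase genes (elo) in 6 of 9 (median -0.96, Fisher adjusted p = 0.0402). Glutathione S-transferase genes (gst) fell in 11 of 19 cases (median -0.69, Fisher adjusted p = 0.00541).

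The sqv genes act in building heparan sulfate chains and chondroitin chains, the latter carried by proteins such as CPG-1 and CPG-2. Of 8 sqv genes tested, 6 rose (median 0.58, Fisher adjusted p = 0.0328), led by sqv-5 at 1.83. Of 7 tested mcm genes, 6 rose (median 1.15), mcm-3 by 1.73 and mcm-6 by 1.59 on the log2 scale; this group was too small for the family test. Small fipr peptide genes rose in 6 of 8 cases (median 1.39, Fisher adjusted p = 0.0328). The counts of risers and fallers in these families did not change with median-of-ratios or upper-quartile scaling. The paralog rpl-42, on chromosome II near rpl-36.A, had 2, 6 and 7 reads in no CHX replicates 1 to 3 and 0 in each CHX library, too few to be tested.

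The rise of oocyte genes with a fall of sperm genes was weighed against 3 explanations. An even gain of all germline tissue would raise the germline list by about as much. Its median was 0.0946 (interquartile range 0.795) against 2.80 for oocyte genes, which argues against such a gain as the source. The list took 0.758% to 0.796% of reads without CHX and 0.804% to 0.898% with it, so a small gain stays open. A larger share of oocytes alone was not tested. Reads shared between near-identical copies would leave the other sperm genes in place. The 20 sperm genes outside the msp, msd, ssp, sss, ssq, nspd and smz families had a median of -0.882, which argues against it. Those 20 were not themselves checked for near-identical copies. Developmental timing within L4 could not be decided. The adult-stage collagen gene col-19 rose by 0.695 on the log2 scale (95% interval 0.367 to 1.02, edgeR adjusted p = 0.0034). In contrast, col-62, at only 8.98 to 16.8 CPM, had 0.422 (-0.141 to 0.984, edgeR adjusted p = 0.219). Both were highest in CHX replicate 2, with 1208 CPM of col-19 against 820 and 966 in the other CHX libraries. Later timing and an effect of CHX on the switch from sperm to oocytes cannot be told apart here, because the CHX animals had been cultured 1 day longer and no other time was used.

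The fall of ribosomal protein genes may belong in part or in full to a trend with abundance. Of random lists matched on CPM and genomic span, 48.5% had a higher median, with a typical value of -0.30. However, without the 100 most abundant genes, 42 of the 54 ribosomal protein genes left fell. Their median was -0.42, against -0.30 for all 80. Within the list, the less abundant members thus fell no less. Those 54 were not compared with matched lists of their own, so these values do not decide whether abundance alone was the source. Matched lists fell less than 3 other lists did. Of them, 100% lay above ribosome biogenesis genes (typical value -0.01, against -0.64). Another 100% lay above mitochondrial ribosomal proteins (-0.05, against -0.39), and 99.9% above nuclear-encoded oxidative phosphorylation (-0.20, against -0.47). Random lists take members as independent, whereas the estimated correlations within these 3 lists were 0.142, 0.196 and 0.287. The shares therefore overstate the certainty that these lists moved beyond the trend with abundance. That trend may account for part of the fall of oxidative phosphorylation genes, and for that of translation factors, where 96.4% lay above. Dilution by the reads that oocyte, eggshell and yolk genes gained is argued against by their size, 0.970 percentage points of a library. Genomic span was used for want of coding length, so a trend with coding length stays open, as do culture time and a lower demand for ribosomes and respiration in CHX-grown animals.

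The heat shock list did not pass, and the fall of 9 of its 17 genes could come from no CHX replicate 3, in which hsp-70 had 415.9 CPM against 161 and 157 in the other no CHX libraries, and hsp-16.2 had 519 CPM against 111 and 170; neither gene passed (edgeR adjusted p = 0.196 and 0.259). Without that library the median of the heat shock list moved from -0.37 to -0.258. A median below -0.25 had been set beforehand as going against that library as the source. The value met this bound, but by less than its bootstrap SE of 0.0358, so it did not decide the question. A still smaller fall had been set beforehand as going with that library as the source, and the median did not shrink that far. The contribution of that library and that of CHX cannot be told apart with 2 no CHX libraries left. No record of stress or handling of single libraries was used here.

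Regrouping the 6 libraries into 3 and 3 allows 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes. It called 4487 genes with edgeR, and the highest of the other splits called 0, with 63 to 227 genes at an unadjusted p under 0.05.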
